A study of Mus musculus with 12 samples.

How the data were processed

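Paraventricular nucleus tissue was taken as micropunches with a 1.0 mm needle from 2 successive brain slices of 300 µm, and stranded poly-A libraries were made from 250 ng of total RNA, per the labels' protocols. The 12 libraries were pooled and run on 2 HiSeq2000 lanes as single-end reads, per the series design and the labels. The authors deposited one table of RPKM values, with 30399 rows for RefSeq transcripts and one column per animal, each named as the animal's title in the labels. The submitters' processing notes name genome build mm9 and edgeR, whose part in making the values is not stated. The aligner, the read counter, their versions and any scaling inside the RPKM values are not given in the sources used here. The list of mitochondrially encoded genes written beforehand had no member in the table.

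The unit was checked on the values. All deposited RPKM values are multiples of 0.00005, as for a mean over 2 lanes of values with 4 decimals, and the lowest values of intronless olfactory receptor genes fall on 2 steps per library. These steps gave the number of reads per lane and library. All low values lay within 2% of a sum of multiples of the 2 steps. This is a weak check, because many of those values also set the steps. Depth ran from 22.8 to 45.2 M reads. Whole reads could not be restored for longer transcripts with shared exons, so a count model was not used.

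A gene with several transcript rows was represented by the row of highest mean, which gave 23256 genes. Of 913 rows without a symbol, 868 were named through their RefSeq accession, and the rest kept their identifier. Rows that share reads (isoforms, overlapping genes, near-identical copies, microRNA precursors inside longer transcripts) were not separated, so values of such rows are uncertain. Groups were taken from the labels. Replicate numbers run from 1 to 6 in miR and from 7 to 12 in PBS. Every pair of libraries differed by more than sampling noise: the median squared difference over genes, in units expected from read counts, was 2.59 or more in all pairs, so no library was counted as a copy of another.

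Values were analysed as log2(RPKM + 0.5) for the 13273 genes with a mean of at least 1 RPKM over all libraries. A fold change on this scale understates the change of genes of low level. The main comparison used limma 3.58.1 in R 4.3.3 (linear model without covariates, empirical Bayes with a variance trend, 2-sided, Benjamini-Hochberg adjusted p below 0.05). Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, 2-sided, over the 33 lists with at least 5 tested members. Each list was also scored per library as the mean of gene-wise z-scores, and scores were compared by a 2-sided exact permutation test over 924 labelings. The whole profile was compared by the pseudo-F of squared Euclidean distances over the same labelings, and principal components were taken from the tested genes. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9.

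The lists, tests, named genes and most alternatives were fixed before the data were examined. Genes named in the text are, for each direction, those past the threshold of largest change or, as here, the 8 of smallest p where fewer than 8 passed. For each list the 2 members of smallest p are the examples, given in full for the lists of the tissue, matrix, vessel and glial cells. Crh, Avp, Oxt, Nr3c1, Nr3c2, Fkbp5, Sgk1, Sirt1, Ube3a, Col1a1, Col1a2, Col4a1, Ttr, Pecam1 and Mbp were always included. The noncoding RNAs, Leng8 and Snrnp70 were named after their values had been seen. Alternatives were pseudocounts of 0.1 and 1 RPKM, no filter and a filter at 5 RPKM, median scaling, quantile normalization, no variance trend, robust empirical Bayes, library weights, an adjusted p of 0.1, covariates for PVN identity and for meninges with choroid plexus, an estimated inter-gene correlation, a Spearman distance, and each library left out. Added after the data were seen were gene values as means over rows, each transcript row by itself, protein-coding rows alone, a correction of each library for its trend with transcript GC content in 20 bins, a covariate for the nuclear-retained RNAs, and each of the 15 pairs of PBS libraries left out. GC content and 3' untranslated regions came from GENCODE M21 transcript sequences matched by RefSeq accession (98.0% of tested genes), and no coordinate of that annotation is printed.

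The scripts were tested on simulated data for miR against PBS with 13273 genes. Of genes changed by 1.41-fold (0.5 on the log2 scale) 86.4% were recovered, and of genes changed by 2-fold 97.4%, with 4.17% of calls false. A list of 20 genes shifted by 0.3 on the log2 scale was called by camera and by the exact score test in 20 of 20 runs, and an unshifted list in 1 and 2 of 20 runs. Simulated genes varied independently of each other, and a list was called at an unadjusted p under 0.05. These rates therefore do not carry over to the real libraries, whose genes vary together (estimated correlation 0.494 in the collagens).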

Results

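The study asked whether a set of microRNAs present in the zygote leaves a trace in the adult hypothalamus. Mouse zygotes of a C57/Bl6:129S6/SvEvTac hybrid background were microinjected with a mixture of 9 microRNA mimics at 1 ng/uL in total and 0.11 ng/uL each or with the phosphate-buffered saline vehicle alone. The mixture held miR-29c and miR-375, the miR-30 family members 30a and 30c, miR-204 and miR-32, and miR-698, miR-532-3p and miR-193-5p. The embryos were carried by CD1 surrogate dams. The paraventricular nucleus (PVN), the hypothalamic nucleus whose neurons start the hormonal stress response, was punched from the brains of the adult male offspring at 18 to 20 weeks of age. Polyadenylated RNA was sequenced from 6 animals of the mimic-injected group (miR, replicates 1 to 6) and 6 animals of the vehicle group (PBS, replicates 7 to 12), described by the series as biological replicates. The labels do not say which animals shared a litter.

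Sequencing depth, read from the steps between the lowest values, was 22.8 to 45.2 M reads per library in the miR group and 27.6 to 38.2 M in the PBS group. The mean was 30.3 ± 8.47 M reads (SD, n = 6) in miR and 32.0 ± 3.57 M (SD, n = 6) in PBS. Levels are given in reads per kilobase of transcript and M reads (RPKM), and coordinates are those of mouse build mm9. A gene entered the tests when its mean over the 12 libraries was at least 1 RPKM, which left 13273 genes. At that level a gene had a median of about 93.9 reads per library.

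No single gene differed between miR and PBS once all tested genes were taken into account. With limma, 0 of 13273 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.124. At an unadjusted p under 0.05 there were 2687 genes, of which 1210 were higher and 1477 lower in miR, where about 664 would be expected with no difference. The lower share was 55.0%, against 41.8% with median-scaled libraries and 68.4% with GC-corrected libraries. These differences were small, and 133 of the 2687 genes exceeded 1.5-fold. In 34 genes every miR library lay above every PBS library and in 30 genes below, which is 0.482% of genes against 0.216% expected by chance. Both expected values, 664 genes and 0.216%, are averages. Because genes vary together, a single count can lie far from them with no difference between the groups. Whether other divisions of the libraries separate as many genes was not tested. The count past the threshold depended on the PBS libraries: limma called 909 genes (243 higher, 666 lower) without PBS replicate 7, 429 genes (104 higher, 325 lower) without PBS replicate 11, and 3107 genes (1578 higher, 1529 lower) without both. Leaving out pairs of PBS libraries was chosen after the data were seen, and the other 14 pairs gave 0 to 3 genes. Weighting each library by its estimated quality gave 3025 genes (1436 higher, 1589 lower). These weights fall where a library departs from its own group, and were lowest in PBS replicates 7, 9 and 11 (0.408, 0.451 and 0.455). Of the 909 genes called without PBS replicate 7, 878 were among the 3025, so the weighted count is not separate evidence.

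The genes with the smallest p-values are described here although none passed the threshold. On the higher side in miR, with adjusted p = 0.174 in limma for each, stood Gjb6, which encodes the astrocyte gap junction protein connexin 30 (chromosome 14, 57742140 to 57752414). It measured 32.8 ± 1.36 RPKM (SD, n = 6) in miR and 28.7 ± 1.10 RPKM in PBS, a log2 difference of 0.19 with a standard error of 0.04. Aif1, which encodes the microglial protein Iba1 (chromosome 17, 35307937 to 35312946), measured 4.17 ± 0.3004 RPKM in miR and 3.17 ± 0.447 RPKM in PBS, a log2 difference of 0.36. C1galt1, a glycosyltransferase of mucin-type O-glycans (chromosome 6, 7795224 to 7822042), measured 5.27 ± 0.716 RPKM and 3.81 ± 0.670 RPKM, a log2 difference of 0.42. The remaining 5 of this side were Scoc, 6330409N04Rik, the zinc finger gene Zfp748, the kinase gene Pdik1l and the angiogenic factor gene Aggf1, at 1.17-fold, 1.19-fold, 1.20-fold, 1.19-fold and 1.14-fold. All 6 miR libraries lay above the PBS median for each of these 8 genes, which is no added evidence in genes picked by their p.

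On the lower side in miR, 4 of the 8 rows of smallest p were precursors of microRNAs, short rows that take up reads of the transcripts they lie in. Mirlet7b (chromosome 15, 85537749 to 85537833) measured 1.52 ± 0.397 RPKM (SD, n = 6) in miR and 4.27 ± 1.40 RPKM in PBS, a log2 difference of -1.21 with a standard error of 0.18 and an adjusted p of 0.124 in limma. Mir5117 (chromosome 1, 162967484 to 162967574), Mir3101 (chromosome 7, 27961025 to 27961112) and Mir1249 (chromosome 15, 84781956 to 84782053) differed by -1.23, -1.65 and -1.29 on the log2 scale, with adjusted p = 0.158, 0.174 and 0.174. Without miR replicate 3, Mir3101 passed alone (adjusted p = 0.0172 in limma). At their short length these 4 rows rest on few reads per library, fewer than the median of about 93.9 of a gene at the filter. Mir3101 ran from 0 to 1.97 RPKM in miR and from 1.66 to 3.03 RPKM in PBS. The other 4 were Fbxl12, an F-box protein gene (4.54 ± 0.665 RPKM in PBS and 3.27 ± 0.228 RPKM in miR), Josd2, a deubiquitinating enzyme gene (18.1 ± 2.71 and 12.4 ± 1.91 RPKM), Fdxr, which encodes mitochondrial ferredoxin reductase (5.42 ± 0.865 and 3.74 ± 0.400 RPKM), and Fcho1, an endocytic adaptor gene (15.9 ± 2.61 and 11.1 ± 1.21 RPKM). Each of these 4 had an adjusted p of 0.174 in limma. All 6 miR libraries lay below the PBS median for the 8 rows, again no added evidence in rows picked by their p.

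Over the whole profile the groups accounted for 19.4% of the variance (pseudo-F 2.41), with an exact permutation p = 0.0433 over the 924 labelings of the 12 libraries. The first principal component held 36.7% of the variance and placed PBS replicates 8, 9, 10 and 12 at 16.5, 18.0, 18.5 and 19.9, while the 6 miR libraries lay between -16.4 and -3.71. PBS replicates 7 and 11 lay among the miR libraries, at -9.94 and -7.69. Across 13004 genes the log2 difference between miR and PBS had a Spearman correlation of -0.636 with transcript GC content, from a set of genes that are not independent replicates. Several noncoding RNAs known to stay in the nucleus divided the PBS group in the same way. Meg3, an imprinted maternally expressed RNA, measured 158, 316, 190 and 245 RPKM in PBS replicates 8, 9, 10 and 12, but 50.6 and 58.0 RPKM in replicates 7 and 11 and 49.9 to 68.1 RPKM in the miR libraries. Miat and Snhg11 had means of 20.8 ± 11.2 and 210 ± 115 RPKM in PBS and 7.49 ± 1.35 and 80.8 ± 17.1 RPKM in miR (SD, n = 6 each). Malat1 reached 57.0 RPKM in PBS replicate 9 and lay between 7.11 and 19.2 RPKM in the other 11 libraries. Rian, a neighbour of Meg3 in the same imprinted cluster, measured 81.8 ± 5.85 RPKM in miR and 88.2 ± 10.2 RPKM in PBS. The division was not confined to noncoding RNAs. The protein-coding gene Leng8 measured 34.5, 38.3, 33.6 and 39.5 RPKM in PBS replicates 8, 9, 10 and 12. It measured 8.78 and 9.97 RPKM in replicates 7 and 11 and 8.13 to 10.4 RPKM in miR. Snrnp70, also protein-coding, measured 80.8, 82.0, 72.8 and 89.8 RPKM in those 4, 46.5 and 47.4 RPKM in replicates 7 and 11, and 38.4 to 46.4 RPKM in miR. The exact permutation p of the whole profile was 0.0649, 0.0866, 0.0736 and 0.0779 without PBS replicate 8, 9, 10 and 12 in turn, and 0.0628 both without miR replicate 5 and with GC-corrected libraries.

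**Figure D1:**
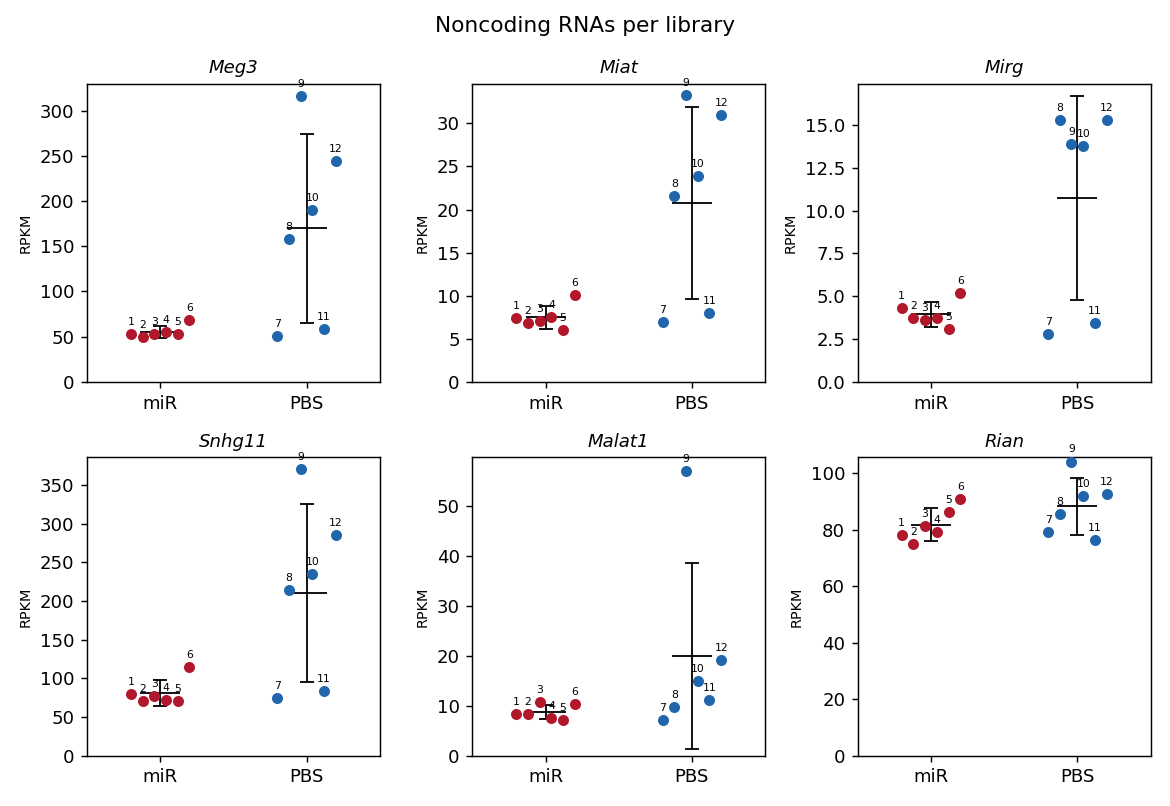
Levels of 6 noncoding RNAs in RPKM (vertical axes, from 0) in the 6 miR libraries (red) and the 6 PBS libraries (blue), with replicate numbers, group means and SD as bars. Meg3 lay at 158 to 316 RPKM in PBS replicates 8, 9, 10 and 12 and at 49.9 to 68.1 RPKM in all other libraries, while Rian lay at 74.8 to 104 RPKM throughout.

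Collagen chains, the structural proteins of basement membranes and connective tissue, were lower in miR as a group. Of the 14 collagen genes tested, 13 had a lower value in miR and 10 an unadjusted p under 0.05 in limma. Their median log2 difference was -0.49, 28.6% less on the scale analysed. The camera test gave an adjusted p of 6.95e-06, and an adjusted p of 0.98 with an estimated correlation between genes. Adjusted over the list alone 9 collagens passed, and over all genes tested none did. The study chose collagen and matrix genes on these same animals, so the list is not independent evidence of its direction. Col16a1 (chromosome 4, 129725084 to 129776521) measured 1.23 ± 0.155 RPKM in miR and 2.98 ± 1.27 RPKM in PBS (SD, n = 6), and Col18a1 (chromosome 10, 76514924 to 76629275) measured 1.22 ± 0.531 and 2.64 ± 1.02 RPKM. Of the basement membrane collagen IV chains, Col4a1 measured 3.32 ± 0.392 RPKM in miR and 4.99 ± 1.57 RPKM in PBS, and Col4a2 4.56 ± 0.396 and 9.36 ± 3.86 RPKM. Of the type I chains, Col1a2 measured 1.60 ± 0.113 and 1.75 ± 0.260 RPKM, and Col1a1 lay below the filter at 0.323 and 0.415 RPKM. The collagen score was 1.10, 1.31, 0.57 and 0.99 in PBS replicates 8, 9, 10 and 12, the libraries with the high Meg3, and -0.52 and -0.46 in PBS replicates 7 and 11, inside the miR range of -0.91 to -0.26. With the score of the nuclear noncoding RNAs as a covariate, the median collagen difference was -0.07 and its adjusted p in camera 0.303.

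Among 26 other matrix genes, 16 were lower and 10 higher in miR, with a median log2 difference of -0.02 and an adjusted p of 0.172 in camera. The 2 of smallest p were Eln, which encodes elastin, at 0.832 ± 0.105 RPKM in miR and 1.73 ± 0.675 RPKM in PBS (SD, n = 6), and Dcn, which encodes the proteoglycan decorin, at 1.99 ± 0.267 and 2.62 ± 0.398 RPKM. Of 16 established targets of the injected miR-29 family, 10 were lower and 6 higher, with a median log2 difference of -0.07 and an adjusted p of 0.222 in camera. Of those 16 genes, 4 are collagens and 5 other matrix genes of the lists above, and the 2 members of smallest p were Eln and Col4a2. Neither list is independent evidence of its direction, for the same reason. The other matrix genes passed in camera without PBS replicate 12 (adjusted p = 0.0386) and without a filter on low values (0.0336), as did the miR-29 targets without that filter (adjusted p = 0.0246). With an estimated correlation both lists had an adjusted p = 0.98.

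Transcripts of blood vessel cells were lower in miR as groups. Of 20 endothelial markers tested 19 had a lower value in miR, with a median log2 difference of -0.14 and an adjusted p of 0.000241 in camera. With an estimated correlation the list had an adjusted p = 0.98 in camera (0.0933 before correction). Cdh5, which encodes the endothelial cadherin, measured 1.73 ± 0.273 RPKM in miR and 2.17 ± 0.209 RPKM in PBS (SD, n = 6). Eng, which encodes endoglin, measured 2.99 ± 0.380 and 3.92 ± 0.767 RPKM. Pecam1 measured 3.64 ± 0.218 and 4.04 ± 0.581 RPKM. All 9 markers of mural cells, the pericytes and smooth muscle cells around vessels, had a lower value in miR. Their median log2 difference was -0.24, with an adjusted p of 0.00339 in camera. With an estimated correlation the mural list had an adjusted p = 0.98 in camera (0.0659 before correction). Among the mural markers Cspg4 measured 2.13 ± 0.193 and 2.61 ± 0.238 RPKM, and Pdgfrb 2.90 ± 0.253 and 3.46 ± 0.459 RPKM. With the nuclear RNA score as a covariate the endothelial list passed in camera (adjusted p = 0.0112) and the mural list did not (adjusted p = 0.0619). The endothelial score was -0.79 in PBS replicate 7 and 0.39 to 0.95 in the other 5 PBS libraries, against -0.93 to 0.12 in miR.

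**Figure D2:**
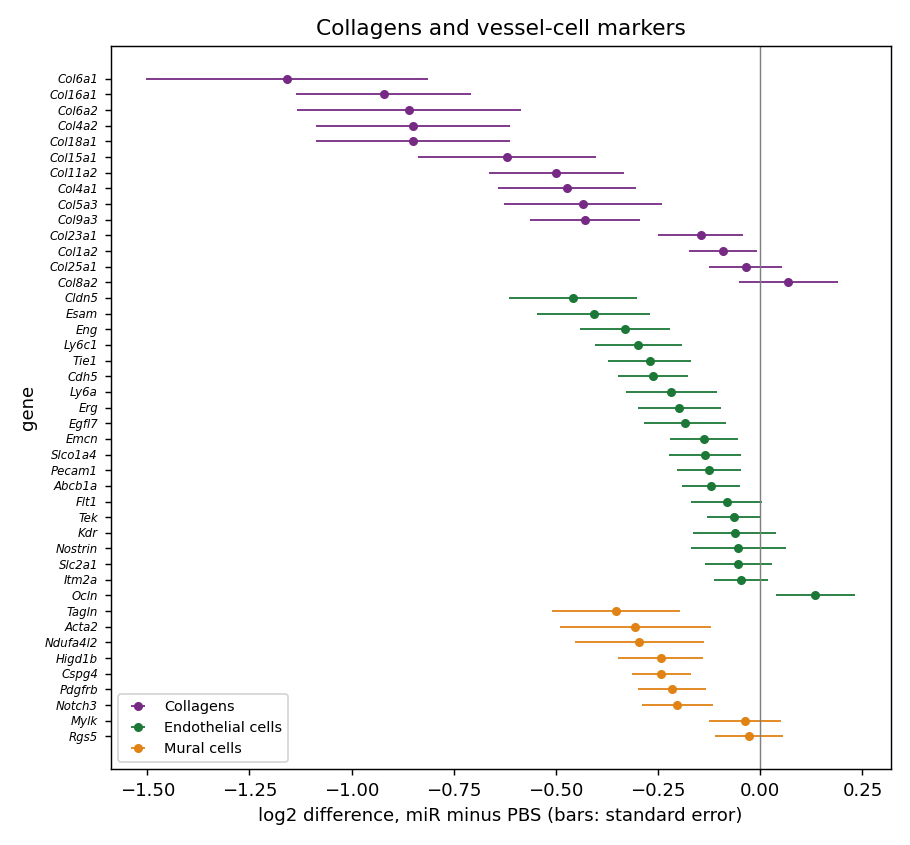
Log2 differences between miR and PBS (horizontal axis, negative where miR is lower) for each tested collagen (purple), endothelial marker (green) and mural marker (orange), with standard errors from limma as bars and 6 animals per group. The collagens ranged from -1.16 (Col6a1) to 0.07 (Col8a2), and no gene passed an adjusted p of 0.05.

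Markers of 2 glial types were higher in miR as groups, by small amounts. Of 18 astrocyte genes 15 had a higher value in miR, with a median log2 difference of 0.09 and an adjusted p of 0.0243 in camera, or an adjusted p = 0.98 with an estimated correlation. Besides Gjb6, the water channel gene Aqp4 measured 28.6 ± 2.26 RPKM in miR and 23.6 ± 4.09 RPKM in PBS (SD, n = 6). Of 17 microglia and macrophage genes 12 had a higher value, with a median log2 difference of 0.09 and an adjusted p of 0.0243 in camera, or an adjusted p = 0.98 with an estimated correlation. Besides Aif1, the Fc receptor gene Fcgr3 measured 5.20 ± 0.353 and 4.35 ± 0.378 RPKM. Both calls were lost when miR replicate 3 or 4 or PBS replicate 9 or 11 was left out, with adjusted p-values in camera from 0.0570 to 0.120. The microglia median was 0.05 without miR replicate 4 or PBS replicate 9, but 0.09 without miR replicate 3 and 0.10 without PBS replicate 11. The astrocyte median was 0.05 without PBS replicate 9, but 0.11 without miR replicate 3 or PBS replicate 11 and 0.10 without miR replicate 4. The astrocyte call was lost also without PBS replicate 10 (adjusted p = 0.0565 in camera). With the nuclear RNA score as a covariate both had an adjusted p of 0.452 in camera, at medians of 0.005 (astrocytes) and -0.01 (microglia). With a filter at 5 RPKM the adjusted p-values in camera were 0.0722 and 0.245, with both medians at 0.09. With quantile-normalized libraries the astrocyte list had 0.153, at a median of 0.08.

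None of the 33 lists passed correction when each was scored per library and the scores were compared by exact permutation. Before correction the mural score had an exact permutation p = 0.0216, the endothelial score 0.0325, the collagen score 0.0346 and the score of meningeal and perivascular fibroblasts 0.0476. Their adjusted values were 0.381, 0.381, 0.381 and 0.393. The fibroblast list had 6 tested members, 3 higher and 3 lower, among them Dcn and Igf2 (3.01 ± 0.627 RPKM in miR and 4.09 ± 0.627 RPKM in PBS, SD, n = 6), and an adjusted p of 0.486 in camera. Random division of the 12 libraries also gave list calls: 80 of 100 divisions had at least as many lists past the camera threshold as the 5 found here, and the highest count was 19.

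**Figure D3:**
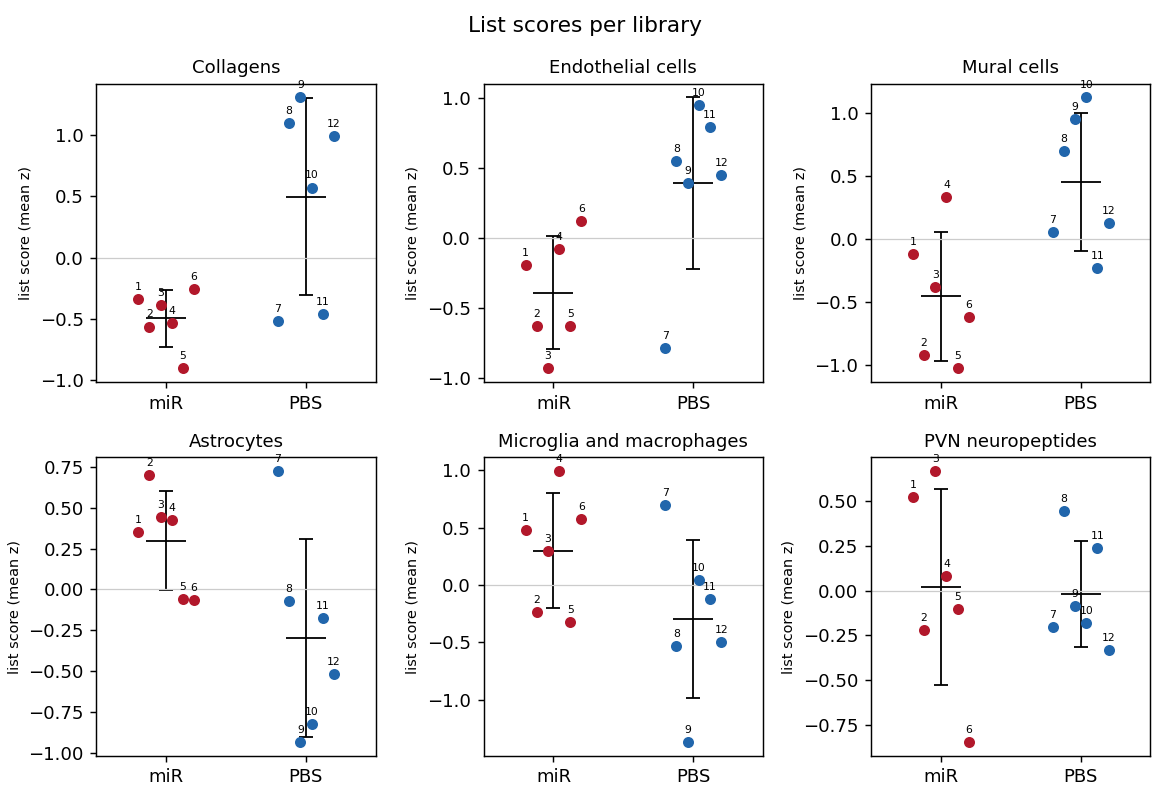
Scores of 6 lists (vertical axes, mean of gene-wise z-scores of log2 RPKM) in the 6 miR libraries (red) and the 6 PBS libraries (blue), with replicate numbers, group means and SD as bars. The collagen scores of PBS replicates 7 and 11 lay at -0.52 and -0.46, within the miR range of -0.91 to -0.26, and the scores of PVN neuropeptides overlapped throughout.

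The neuroendocrine identity of the tissue did not differ detectably between the groups. Oxt, which encodes oxytocin (chromosome 2, 130401909 to 130402724), measured 2703 ± 942 RPKM in miR and 2646 ± 1010 RPKM in PBS (SD, n = 6), and Avp, which encodes vasopressin (chromosome 2, 130406413 to 130408277), measured 800 ± 246 and 1039 ± 382 RPKM. Crh, which encodes corticotropin-releasing hormone, the releasing factor of the stress axis (chromosome 3, 19593401 to 19595396), measured 10.3 ± 1.32 and 14.1 ± 5.11 RPKM, a log2 difference of -0.34 with a standard error of 0.23 and an adjusted p of 0.406 in limma. Without PBS replicate 7 Crh passed, at a log2 difference of -0.59 and an adjusted p of 0.0255, and Avp differed by -0.59 with an adjusted p of 0.0716, against -0.32 in all libraries and -0.17 without PBS replicate 11 (adjusted p = 0.718). Of 18 PVN neuropeptide and secretory genes 10 had a higher and 8 a lower value in miR (adjusted p of 0.975 in camera). Its 2 members of smallest p were the processing enzyme gene Pcsk1 (36.1 ± 3.91 and 31.4 ± 7.47 RPKM) and the granin gene Scg2 (421 ± 24.97 and 394 ± 23.8 RPKM). Of 9 genes listed as PVN transcription factors 6 had a higher and 3 a lower value (adjusted p of 0.909 in camera). The 2 of smallest p were Rora (8.05 ± 1.61 and 6.56 ± 1.43 RPKM) and Fezf2 (2.44 ± 0.207 and 3.31 ± 1.17 RPKM). Rora is also in the list of the neighbouring thalamus, so it does not mark the PVN alone. Fezf2 passed without PBS replicate 7 (adjusted p = 0.0243 in limma).

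Receptors and regulators of the stress axis likewise gave no call. Of 18 such genes 11 had a higher and 7 a lower value in miR (adjusted p of 0.653 in camera). The glucocorticoid receptor gene Nr3c1 measured 22.6 ± 1.20 RPKM in miR and 20.9 ± 2.84 RPKM in PBS (SD, n = 6), and the mineralocorticoid receptor gene Nr3c2 5.03 ± 0.358 and 4.63 ± 0.531 RPKM. Fkbp5, which encodes a receptor co-chaperone, measured 6.42 ± 0.431 and 6.26 ± 0.379 RPKM. The members of smallest p were the chaperone gene Hsp90aa1 (78.9 ± 4.98 and 67.6 ± 7.96 RPKM) and the transcription factor gene Creb3l1 (2.12 ± 0.333 and 2.72 ± 0.361 RPKM), each with an adjusted p of 0.174 in limma. Of 15 genes induced by glucocorticoids 10 had a higher and 5 a lower value (adjusted p of 0.504 in camera). Sgk1 measured 6.89 ± 0.967 and 6.48 ± 1.17 RPKM, the metallothionein gene Mt2 81.9 ± 14.6 and 67.0 ± 4.55 RPKM, and Klf9 15.5 ± 0.855 and 13.2 ± 2.18 RPKM.

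Markers of other cells and of neighbouring regions were used to ask whether the punches differed in content. Myelin genes numbered 15 higher and 4 lower of 19 (adjusted p of 0.549 in camera), and Mbp, which encodes myelin basic protein, measured 361 ± 81.0 RPKM in miR and 345 ± 216 RPKM in PBS (SD, n = 6). Without PBS replicate 7 the myelin list passed, at a median log2 difference of 0.33 and an adjusted p of 0.000391 in camera. With an estimated correlation, 0.840 between these genes, and all libraries its adjusted p = 0.98. Oligodendrocyte precursor genes divided 5 and 5 (adjusted p of 0.909), choroid plexus genes 4 and 4 (0.657), and ependymal and tanycyte genes 11 higher and 4 lower (0.222, but 0.0145 without miR replicate 5 and 0.0249 with GC-corrected libraries, and 0.98 with an estimated correlation). The choroid plexus marker Ttr lay below the filter, at 0.443 ± 0.162 RPKM in miR and 0.307 ± 0.0592 RPKM in PBS. All 6 blood transcripts had a higher value in miR (adjusted p of 0.486), with the globin genes Hbb-b1 and Hbb-b2 at a log2 difference of 0.36 and 0.37, or 0.20 each without miR replicate 5 and 0.51 each without miR replicate 4. These neighbouring globin genes share most of their sequence, so their values are not separate measurements. Pan-neuronal genes divided 11 higher and 7 lower (adjusted p of 0.657), GABAergic genes 9 and 3 (0.653) and glutamatergic genes 5 and 4 (0.822). Thalamic genes divided 5 higher and 7 lower (0.909), striatal and basal forebrain genes 7 and 4 (0.975), and genes of other hypothalamic nuclei 7 and 6 (0.861).

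The remaining lists gave no call in camera. Interferon and antigen presentation genes were 12 higher and 6 lower in miR (median log2 difference 0.18, adjusted p of 0.163), with Ifit1 at 1.92 ± 1.52 RPKM in miR and 0.700 ± 0.186 RPKM in PBS (SD, n = 6). Nuclear-encoded respiratory chain genes were 38 higher and 9 lower (adjusted p of 0.118), and ribosomal protein genes 57 higher and 18 lower (adjusted p of 0.161). With an estimated correlation these 3 lists had an adjusted p = 0.98. At the preset correlation, leaving out single libraries brought each past the threshold in camera: the interferon genes without miR replicate 1 or 2 (adjusted p = 0.0285 and 0.0131), the respiratory chain without miR replicate 2 or PBS replicate 10 or 12 (0.0194, 0.0290 and 0.000654), and the ribosomal proteins without miR replicate 2 or PBS replicate 12 (0.0131 and 0.00200). Likewise at the preset correlation, with GC-corrected libraries all 3 passed (adjusted p = 0.00523, 5.66e-05 and 0.0105), and with the nuclear RNA score as a covariate the interferon genes did (4.50e-07). Without a filter on low values the respiratory chain and ribosomal proteins passed (0.0257 and 0.0376), as did the ribosomal proteins with a filter at 5 RPKM (0.0391). Chromatin and DNA methylation enzymes were 9 higher and 17 lower (adjusted p of 0.198). Within that list the deacetylase gene Sirt1 measured 3.94 ± 0.279 and 3.72 ± 0.241 RPKM and the ubiquitin ligase gene Ube3a 25.5 ± 2.92 and 21.6 ± 3.45 RPKM, with adjusted p = 0.497 and 0.219 in limma. Growth-factor genes divided 13 higher and 11 lower (0.657), small RNA machinery genes 6 and 8 (0.651), stress chaperones 6 and 8 (0.486), circadian clock genes 7 and 11 (0.909), synaptic vesicle genes 11 and 9 (0.909) and immediate early genes 7 and 10 (0.909).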

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

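For the nuclear RNAs, the tests of GC content on the list alone, genomic DNA, swapped labels, an even rise, unspliced RNA and the imprinted locus were chosen after the pattern or related values had been seen, as were the comparison of collagen with endothelial genes and the nuclear lists without single libraries. The test of unspliced RNA was computed before its prediction was written, and of the 9 tests of the nuclear RNAs it is the only one that met its prediction. The tests of sequencing depth and of the imprinted locus were taken out once their results were known and then put back, so all tests run on the pattern are given.

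Meg3, Miat, Snhg11 and 4 other nuclear noncoding RNAs were chosen after their values had been seen. The high values lay in PBS replicates 8, 9, 10 and 12. Malat1 (9.83 RPKM) and Rian (85.4 RPKM) in PBS replicate 8 were exceptions, each inside its miR range. Neat1 in PBS replicate 7 (7.18 RPKM) and Malat1 in PBS replicate 11 (11.2 RPKM) were exceptions too. They lay above the highest miR values, 5.92 RPKM for Neat1 and 10.7 RPKM for Malat1. The 7 RNAs had a median log2 difference of -1.09 between miR and PBS. Correction for GC content left 96.2% of it over the 6 members with a known sequence (-1.13 to -1.08). The correction takes away only shifts shared by genes of like GC content. Those were small, with median log2 differences of 0.124 among genes of lowest and -0.135 among genes of highest GC content. It could not have removed most of -1.13, so it cannot decide on a GC effect stronger in these RNAs. The median over 3 pooled nuclear lists, which is near 0, went from -0.11 to -0.20 (186%) and says little on these RNAs. Depth as a covariate left 98.1% of the score difference, and olfactory receptor genes, a gauge of genomic DNA, reached 0.00641 RPKM. Depth and genomic DNA were therefore not borne out. The count of 0 miR libraries above the PBS median restates the pattern and leaves swapped labels open. A general rise of nuclear RNA stayed undecided. A list of 13 other noncoding RNAs, written down as nuclear, had a median log2 difference of 0.01 (0.00637, exact permutation p = 0.833, 2-sided), too small for an even rise of these RNAs. The list holds Gas5, Snhg1 and Snhg12, and how far its members stay in the nucleus was not tested. It therefore cannot decide on nuclear RNA as a whole. Of 21 detained-intron mRNAs, 20 were lower in miR (exact permutation p = 0.0606). Their score difference was -0.82, and was -0.59 without PBS replicate 9 (exact permutation p = 0.147) and -1.02 without PBS replicate 7 (exact permutation p = 0.00649). A change of the whole imprinted locus of Meg3 was not borne out by Rian, whose log2 difference was 7.86% of that of Meg3, although Mirg in the same locus measured 3.94 RPKM in miR and 10.7 RPKM in PBS, and Miat and Snhg11, which had lower means in miR too, lie on other chromosomes. The score of microRNA precursors, 74 of 109 lower in miR, met the prediction for more unspliced RNA in PBS (exact permutation p = 0.00649, 2-sided), but precursors among the genes of smallest p had prompted that test and PBS replicate 11, with low Meg3, scored 0.11, level with replicates 8 (0.11) and 10 (0.12), so the cause stays open, as does a biological difference, untested.

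With the score of the nuclear RNAs as a covariate the collagens kept 13.6% of their median log2 difference, the mural markers 54.1% and the endothelial markers 61.2%. This is not specific to collagens and leaves open whether the 2 patterns share a cause, because those RNAs were chosen for their difference between the libraries: with the same covariate the genes at an unadjusted p under 0.05 went from 2687 to 171 and the microglia median from 0.09 to -0.01. Fewer vessel cells in the punches stays open as well. The collagens differed by more than the endothelial markers (difference of medians -0.35, 95% interval -0.72 to -0.04), but that interval treats genes as independent, which they are not, and the mural markers, with a median of -0.24, were not compared. A biological difference between the groups stays open, untested.

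The 12 libraries were divided into 6 and 6 in 100 ways including the real one. All 100 met the real count of 0 genes past an adjusted p of 0.05, as any division must, and the highest other count was 1265. At an unadjusted p under 0.05, 5 of 100 gave at least the real 2687 (highest other 4156), and for lists 80 of 100 gave at least the real 5 (highest other 19). The division with 1265 and 4156 genes placed PBS replicate 7 with miR replicates 1, 2, 4, 5 and 6. A grouping of the animals unrelated to the injection, such as litter or handling, could give counts like these, and no label allows a test of it.

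Single libraries far from the other 5 of their group were found in 26 of 244 groups examined, where chance flags about 1 in 20 groups, or about 12.2 here. PBS replicate 7 stood apart for Mbp (767 RPKM, others 184 to 328), Apod (25.7 RPKM), Pdgfra (14.3 RPKM) and Clic6 (7.19 RPKM), and for the scores of oligodendrocytes (2.12), their precursors (1.07), endothelial cells (-0.79) and interferon genes (-1.07). PBS replicate 11 stood apart for Scoc (43.6 RPKM), Hsp90aa1 (83.02 RPKM) and Elavl4 (34.8 RPKM). PBS replicate 9 stood apart for Uqcrc2 (90.7 RPKM) and the respiratory chain score (-1.95). PBS replicate 10 stood apart for Slc17a7 (19.3 RPKM, others 0.213 to 1.29), Vip (0.833 RPKM) and the synaptic vesicle score (0.85), and PBS replicate 12 for Ifit1 (1.063 RPKM). Among the miR libraries, replicate 5 stood apart for Vip (21.7 RPKM, others 0.164 to 0.396), Scoc (50.6 RPKM) and Homer1 (6.05 RPKM), and replicate 2 for Pmch (67.9 RPKM, others 0.867 to 3.74). Replicate 4 stood apart for Slc17a7 (1.19 RPKM) and the score of striatum and basal forebrain (-0.58), replicate 6 for Ifit1 (4.93 RPKM) and Cox7a2 (120.0 RPKM), and replicate 3 for Clock (11.2 RPKM).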

How the results depend on the processing

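No test chosen after the result was seen stands in this part, but the alternatives for GC content, the nuclear RNA score, transcript rows, protein-coding genes and pairs of PBS libraries were chosen after seeing the data. No paired analysis was possible because the replicate numbers of the 2 groups do not overlap. Of the values of named genes under the alternatives, 2262 kept direction and side of the threshold, 111 newly passed and 18 changed sign without passing before or after. Of the list values 739 kept both, 21 no longer passed, 20 newly passed and 74 changed direction in camera without passing before or after, the PVN neuropeptides and Oxt among the results of unstable sign. No gene or list that passed in the main analysis or in an alternative had opposite directions in the tests of the 2, though the microglia median was -0.01 with the nuclear RNA covariate. No list score passed under any alternative.

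The count of genes past an adjusted p of 0.05 in limma (0 of 13273, 2687 unadjusted) was 3025 with library weights, 1 with the covariate for meninges and choroid plexus, Mirlet7b, and 0 to 909 in leave-one-out fits, with 429 without PBS replicate 11. With pairs of PBS libraries left out it was 0 at the lowest and 3107 at the highest. The count at an unadjusted p under 0.05 was 5066 with library weights, 1546 with GC-corrected libraries, 171 with the nuclear RNA covariate, 892 to 4990 with pairs of PBS libraries left out and 1742 to 3764 in leave-one-out fits. The count of lists in camera (5) was 9 without a filter, 2 with a filter at 5 RPKM, 0 with an estimated correlation, 9 with GC-corrected libraries, 2 with the nuclear RNA covariate and 3 to 8 in leave-one-out fits. The exact permutation p of the whole profile (0.0433) was 0.0628 with GC-corrected libraries and 0.0108 to 0.0866 in leave-one-out fits. In leave-one-out fits the log2 difference of Oxt ran from -0.09 to 0.22, of Mbp from 0.08 to 0.49, of Nr3c1 from 0.07 to 0.19, of Nr3c2 from 0.06 to 0.15, of Col1a2 from -0.13 to -0.05 and of Pecam1 from -0.17 to -0.06. The medians of interferon genes ran from 0.11 to 0.24, of other matrix genes from -0.05 to -0.01 and of miR-29 targets from -0.10 to -0.03. The filter changes which genes are tested, and for the other changes the cause was not tested. Depth limits the rarest genes, since a gene at the filter had a median of about 93.9 reads per library. The short microRNA precursor rows named above had fewer.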

Other observations

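The seed site tests were chosen before their results were seen, and the values of single genes in this part were chosen after they were seen. Fos and Egr1, transcripts induced by neuronal activity, varied widely within both groups. Homer1, also in the list of immediate early genes, varied less (5.28 ± 0.396 RPKM in miR and 4.81 ± 0.478 RPKM in PBS, SD, n = 6). That value is the row of highest mean among its 3 transcript rows, and the others may vary differently. Fos, an immediate early gene, measured 57.3 and 46.5 RPKM in miR replicates 2 and 6 and 57.3, 32.5 and 19.6 RPKM in PBS replicates 8, 12 and 10, against 2.19 to 9.12 RPKM in the other 7 libraries. Egr1 measured 43.0 and 39.98 RPKM in miR replicates 2 and 6 and 46.3, 28.3 and 21.4 RPKM in PBS replicates 8, 12 and 10. Xist, the RNA of the inactive X chromosome, measured 0.448 RPKM in PBS replicate 10 and at most 0.0450 RPKM in the other libraries, and the Y-linked gene Ddx3y measured 17.4 to 27.6 RPKM in all 12.

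Whether sites for the injected microRNAs in 3' untranslated regions go with lower levels in adult PVN was tested with adjustment for length, GC content and level. The 2-sided exact permutation p was 0.158 for miR-29, 0.535 for miR-30, 0.359 for miR-32, 0.894 for miR-204, 0.846 for miR-375 and 0.615 for miR-532-3p. The adjusted log2 difference for miR-29 was -0.01, and each of the 6 had an adjusted p of 0.894. The tests left the hypothesis undecided, because only a rise with an exact permutation p under 0.05 was set to count against it. Over the labelings, the central 95% of adjusted log2 differences spanned -0.016 to 0.016 for miR-29, the widest of the 6. The span was -0.0069 to 0.0069 for miR-532-3p, the narrowest. None of the 6 adjusted differences lay outside its span. Sites of miR-193-5p and miR-698 were not analysed here.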
